A study of Drosophila melanogaster with 10 samples.

How the data were processed

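The deposited table held 1 value per gene and library, for 15422 genes in 10 libraries of embryonic polyA RNA read as single reads of 50 bases. Per the submitters' processing notes, the values are log2 of total RPKM (reads per kilobase of transcript and megaread mapped) on the Drosophila genome build BDGP6. The aligner, the counting tool, the annotation release and whether counting respected the strand are not given in the sources used here. Genes without reads carried the deposited floor value of −9.10916, which lies 1.0 below the lowest other value of −8.10916. In the text such a gene is listed at 0 RPKM. A total of 977 genes stood at the floor in all 10 libraries and 11585 stood above it in all of them. In addition, 158 genes shared all 10 values with another gene, and 5 gene names had been turned into calendar dates.

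Gene names were matched to the FlyBase annotation to obtain identifiers, positions and exon lengths. In total 11814 names were current symbols, 3397 matched 1 gene by an older symbol and 211 had no unique match. Names without a unique match stayed in all tests but have no position or length. Genes overlapping a neighbour carry an uncertain value where reads of both strands may have been pooled.

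The labels give only the range of sequencing depth over all samples, 20.7 to 43.4 megareads. Counted reads per library were therefore estimated from genes with few reads, whose values differ by whole-number ratios. In every library at least 84.5% of the low genes compared gave such a ratio within a tolerance of 0.003 log2. At the depth chosen for control 1, 138 genes stood within 0.005 reads of 1 read, against 10 at double that depth. These estimates were used only to describe depth.

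Genes with at least 1 RPKM in at least 2 of the 10 libraries were tested, which left 10396 genes, 10252 of them with an exon length. The deposited log2 RPKM values were fitted without further scaling in limma 3.58.1 under R 4.3.3, with 1 mean per genotype over all 10 libraries. Moderated tests used a mean-variance trend (prior degrees of freedom 4.73, median total 9.73). Benjamini-Hochberg adjustment ran over all genes tested within a comparison, and a gene was called changed at an adjusted p under 0.05. Differences among the 3 stabilized forms were tested with limma's moderated F test. All p-values are two-sided. Intervals of single genes are 95% intervals from the same fit.

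Gene lists were tested with limma's camera at its preset correlation of 0.01, with adjustment over the 20 lists within each of 8 comparisons, or 160 tests. Camera with a correlation estimated from the residuals was run beside it. The lists covered apoptosis, Cullin ligase subunits and degron readers, cuticle and epidermal secretion, cyclins with their kinases and regulators of S-phase entry, DNA damage and repair, DNA replication and nucleotide supply, fat body and yolk, germ cells, glia, and gut with Malpighian tubule. The others covered hemocytes and basement membrane, mitosis and chromosome segregation, muscle, neuroblast and progenitor factors, neuronal and synaptic genes, neuropeptides, salivary gland and trachea, stress and heat shock, temporal and spatial neural patterning, and markers of transgenes and strains. Members called over all genes and members called when adjusted over the list alone were both counted.

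Named genes followed a fixed rule. The gene dap, encoded by the transgenes, came first, then CycE and ago from the series title. For each form against the control, the 8 largest called changes in each direction were eligible where both libraries lay on 1 side of both controls, together with up to 3 called members of each list. In the other comparisons the 5 largest called changes in each direction were eligible. The text names a part of those genes. Genes named from the set changed in all 4 forms, and genes outside the rule, were chosen after their values were seen.

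The groups, tests, filter, gene lists and naming rule were fixed before the data were examined, as were most of the alternatives. Those chosen beforehand were log2(RPKM + 1), no filter, a filter at a mean of 5 RPKM, quantile normalization, centring each library on its median, no mean-variance trend, a block for replicate number, a fit of only the groups compared, and leaving out each library in turn. A library left alone in its genotype was assumed to vary like the other groups. Leaving out a library also lowers the power to call a change. A lost call therefore does not by itself show that the values of that library had decided it. A correction for exon length and a restriction to genes above the floor in every library were added after the data had been seen. The correction subtracted from each library a lowess trend of its deviation from the mean of all libraries on log exon length, with a span of 0.3.

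Since the 4 comparisons with the control share its 2 libraries, their joint calls were compared with 100 simulations without any change between genotypes. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 prepared the tables and figures.

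The procedure was tested on simulated data with the layout of dapCDI against control. Changes of log2 0.5 were called in 27 of 67 genes (40.3%), changes of log2 1 in 58 of 67 (86.6%) and changes of log2 2 in 60 of 66 (90.9%), with 8 false calls among 153. A list of 47 genes shifted by −0.40 was recovered with a median of −0.42, while 1 other list was also called. The simulated genes varied independently of each other. In the real data the estimated correlation between members was 0.16 for the mitosis list and 0.57 for the neuronal list. These runs therefore do not show how often genes or lists are falsely called in the real data. A length trend alone gave 3924 calls, 3763 of them false, and the correction left 161 calls with 13 false.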

Results

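Gene expression was measured by polyA RNA sequencing in whole embryos of stages 15 to 16, in a series set up to overexpress dacapo. Dacapo is the fly member of the p21/p27 family of inhibitors of cyclin-dependent kinases. Control embryos carried the prospero-Gal4 driver alone, and the other genotypes added a UAS transgene. The transgene encoded wild-type dacapo (dap) or 1 of 3 forms that the labels describe as stabilized, here named dapCRL4, dapPCNA and dapCDI as in the labels. Each of the 5 genotypes had 2 libraries, called independent samples in the labels. No ago mutant was among them, although the series title names that genotype. Estimated depth, in counted megareads (Mreads), was 25.7 and 25.2 in the control libraries, 20.7 and 20.9 in dap, 19.9 and 22.5 in dapCRL4, 21.4 and 17.6 in dapPCNA, and 17.0 and 19.9 in dapCDI. At such depths 1 RPKM on a transcript of 1 kb corresponds to about as many reads as the library has Mreads.

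The gene dap (FBgn0010316, chromosome arm 2R, positions 9712321 to 9716256, BDGP6) was listed at 70.5 and 70.7 RPKM in the control libraries. It stood at 85.8 and 83.4 RPKM in dap, at 81.0 and 75.7 RPKM in dapCRL4, at 70.7 and 73.3 RPKM in dapPCNA, and at 170.2 and 156 RPKM in dapCDI. In dapCDI it rose 2.31-fold over the control, from 70.6 ± 0.117 to 163 ± 9.88 RPKM (SD, n = 2), a log2 change of 1.21 with a 95% interval of 1.06 to 1.36 (limma adjusted p = 2.28e-05). In dap the log2 change was 0.26 with an interval of 0.11 to 0.41 (limma adjusted p = 0.0405). That call was lost when either control library, either dap library, either dapPCNA library or either dapCRL4 library was left out, with an adjusted p of up to 0.175 without control 2, and was at 0.0507 after length correction. It was also lost without a filter, under quantile normalization and without a mean-variance trend. The change did not pass in dapCRL4 at 0.15 (interval −0.00 to 0.30, adjusted p = 0.319) or in dapPCNA at 0.03 (interval −0.12 to 0.18, adjusted p = 0.918). Whether reads from the transgenes count towards dap is not given, so these values need not equal the total of dacapo RNA.

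The series title states that Cyclin E levels rise, and its gene CycE (2L, 15727581 to 15748150) was examined for a change in its RNA. Those levels may be of the protein, which was not measured here and need not follow the RNA. A change in only part of the cells would also be diluted in whole embryos. CycE stood at 12.3 ± 1.60 RPKM in the control, 13.3 ± 2.36 in dap, 12.7 ± 1.24 in dapCRL4, 12.2 ± 0.763 in dapPCNA and 11.8 ± 0.562 in dapCDI (SD, n = 2 each). The log2 changes against the control were 0.10 (interval −0.21 to 0.42) in dap, 0.05 (−0.27 to 0.36) in dapCRL4, −0.01 (−0.33 to 0.31) in dapPCNA and −0.06 (−0.38 to 0.26) in dapCDI. None passed, with limma adjusted p of 0.642, 0.915, 0.989 and 0.807. CycE overlaps annotated antisense and long non-coding genes, so its value may include their reads.

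The gene ago (3L, 4246343 to 4254306) encodes the F-box protein that marks Cyclin E for destruction. Its RNA fell by 0.33 log2 in dap (limma adjusted p = 0.0392) and by 0.39 in dapCDI (adjusted p = 0.0390), from 43.6 ± 0.118 RPKM in the control to 34.7 ± 1.84 and 33.4 ± 3.18 (SD, n = 2). The changes of −0.18 in dapCRL4 and −0.16 in dapPCNA did not pass, with adjusted p of 0.343 and 0.525. Both calls were lost after correction for exon length, where the changes were −0.09 (adjusted p = 0.383) and −0.15 (adjusted p = 0.153). Leaving out dap 2 ended the call in dap, and leaving out dapCDI 1 ended that in dapCDI. Both calls were also lost without a filter and without a mean-variance trend.

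**Figure D1:**
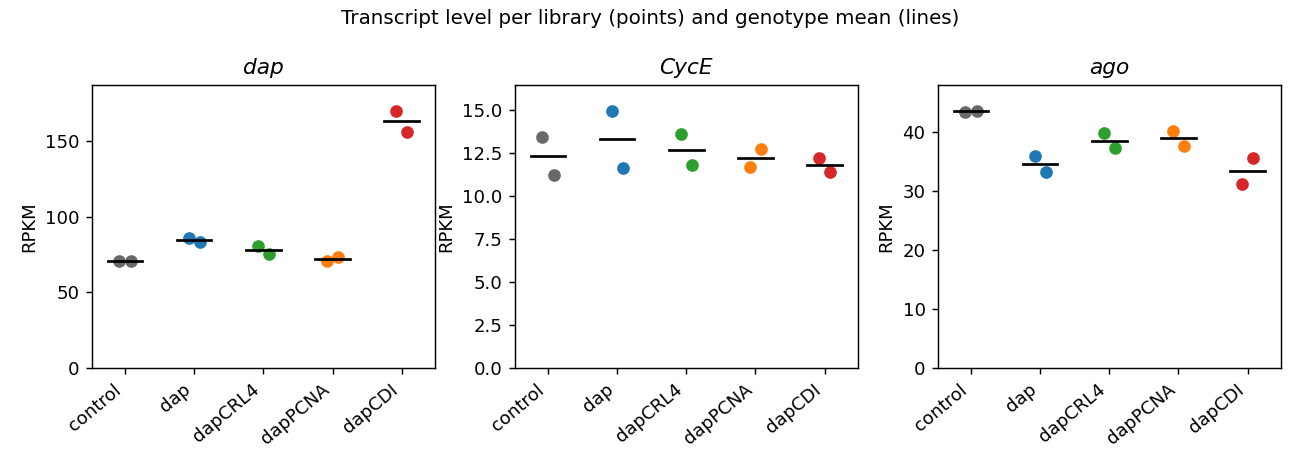
RPKM of dap, CycE and ago (vertical axes) in each of the 10 libraries, grouped by genotype (horizontal axes), with points for libraries and lines for the mean of each genotype. For dap, both dapCDI libraries (170.2 and 156 RPKM) lie above all others, the highest of which is 85.8 RPKM.

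Replicates differed by a median of 0.0955 log2 in the control, 0.127 in dap, 0.0994 in dapCRL4, 0.0909 in dapPCNA and 0.171 in dapCDI. Changes between genotypes followed exon length. Across genes, which are not independent replicates, Spearman's rho between exon length and the change against the control was −0.572 in dap, −0.548 in dapCDI, −0.299 in dapCRL4 and −0.216 in dapPCNA. The fifth of genes with the shortest transcripts had a median change of 0.26 in dap and 0.23 in dapCDI. The fifth with the longest had −0.21 in dap and −0.22 in dapCDI. Replicates of 1 genotype also differed along length, with a rho of 0.446 in dapCDI, −0.340 in dap and in dapCRL4, −0.269 in dapPCNA and −0.0333 in the control. Values after correction for this trend are given for the genes and lists named below where it ended a call.

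**Figure D2:**
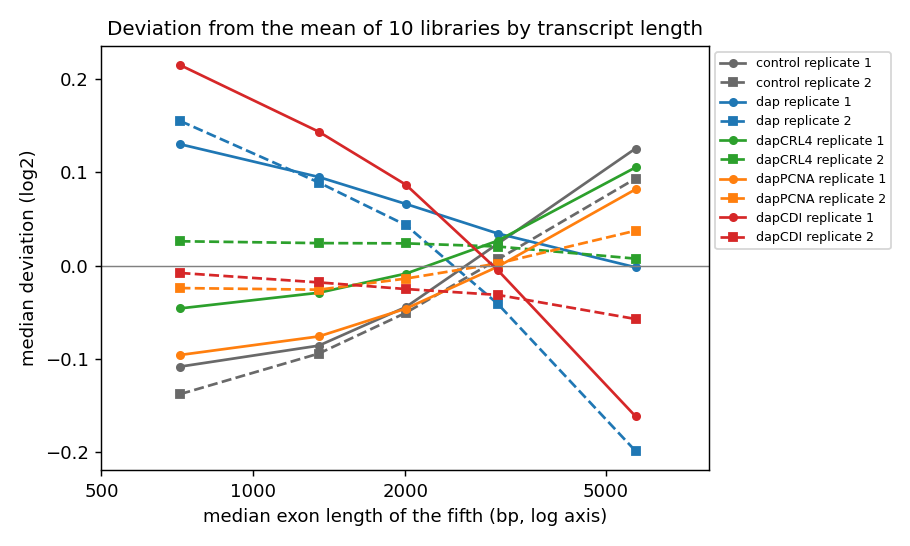
Median deviation from the mean of the 10 libraries (vertical axis, log2 RPKM) for 5 groups of genes by exon length (horizontal axis, bases, log scale), with 1 line per library. The lines of dapCDI 1 (0.21 to −0.16) and dap 2 (0.15 to −0.20) fall furthest from the shortest to the longest group.

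Wild-type dacapo was compared with the driver-only control to find the response to raised dacapo. In dap, 887 genes rose and 340 fell among 10396 tested, while 9169 were not called, and 112 of the calls were at least 2-fold. The calls named next held in every setting and with any library left out, down to that of PH4alphaSG2, except that p24-2, at 0 in a control library, was not tested among genes above the floor in every library. CG31219, a predicted serine protease (3R, 19651018 to 19652430), rose 15.7-fold from 0.887 ± 0.0678 to 13.9 ± 0.893 RPKM (SD, n = 2; log2 3.97, SE 0.11, limma adjusted p = 1.51e-07), although it overlaps CG6184. CG8539 (3L, 7497211 to 7498831) rose 16.7-fold (log2 4.07, adjusted p = 3.14e-05), and CG30148 (2R, 20546595 to 20547658) rose 9.92-fold (log2 3.31, adjusted p = 3.78e-05). The pigment gene yellow (y; X, 356509 to 361245) rose 14.5-fold from 0.157 ± 0.0533 to 2.23 ± 0.450 RPKM (adjusted p = 0.000149). Since y belongs to the list of transgene and strain markers, its rise in each form cannot be told apart from a strain difference. The same limit holds for every gene called in all 4 forms. Of the genes named here these are CG31219, CG8539, p24-2, MtnA, CG11700, CG8100 and PH4alphaSG2. The cargo receptor gene p24-2 (3R, 9687402 to 9692794), which overlaps Unc-115b, was listed at 0 and 0.0539 RPKM in the control and at 12.8 and 9.62 RPKM in dap. Metallothionein MtnA (3R, 9783407 to 9784370) rose 2.09-fold from 622 ± 65.0 RPKM (log2 1.06, adjusted p = 0.00055). The largest falls of this kind were 7.76-fold for CG11700, a ubiquitin-like gene (X, 6282037 to 6283575; adjusted p = 0.00242), 4.70-fold for CG8100 (3L, 14083615 to 14086421; adjusted p = 0.00226) and 4.49-fold for CG33128, a predicted aspartic protease (2L, 1494070 to 1495456; adjusted p = 0.00148). The prolyl hydroxylase gene PH4alphaSG2, of the salivary gland and tracheal list (3R, 30490074 to 30491987), which overlaps PH4alphaMP, fell 2.27-fold from 56.5 ± 7.07 to 24.8 ± 0.956 RPKM (log2 −1.18, adjusted p = 0.000164). The small heat-shock gene Hsp27, which overlaps CR43483, fell from 519.5 ± 120.0 to 172 ± 75.2 RPKM (log2 −1.64, adjusted p = 0.0241). Its call was lost without control 1, control 2 or dap 2, with an adjusted p of up to 0.165, and without a filter or a mean-variance trend.

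Genes of DNA replication and nucleotide supply rose as a list in dap, with a median of 0.26 over 49 genes (camera adjusted p = 1.36e-05; adjusted p = 0.773 with an estimated correlation). Of its members, 7 were called higher and none lower over all genes, and 14 higher when adjusted over the list alone. They included Ts, which overlaps Rbp9 and encodes thymidylate synthase (8.44 ± 0.227 to 13.4 ± 0.845 RPKM; log2 0.67, limma adjusted p = 0.00903). They also included Pole2, a subunit of DNA polymerase epsilon (log2 0.79, adjusted p = 0.0141), and the GINS subunit Psf1 (log2 0.80, adjusted p = 0.0204). Without control 2 the adjusted p was 0.0877 for Ts. The call of Pole2 was lost without control 2 or dap 2 (up to 0.114), and that of Psf1 without either control or either dap library (up to 0.122), after length correction (0.0525) and without a filter or a mean-variance trend. Neuronal and synaptic genes fell with a median of −0.37 over 39 genes (camera adjusted p = 1.14e-07; adjusted p = 0.773 with an estimated correlation), and 4 members were called lower over all genes as well as adjusted over the list alone. The list has a median exon length of 7557 bases against 2007.5 for all genes tested, and after length correction its median was −0.10 (adjusted p = 0.021). The fall rested largely on dap 2, and was −0.19 without it (6.17e-05). The list median deviated from the mean of all libraries by 0.18 and 0.17 in the controls, 0.04 in dap 1 and −0.36 in dap 2, and after length correction by 0.07 and 0.03, 0.09 and −0.15. Its members futsch, ple and Shab fell by 0.91, 0.40 and 0.48 log2 as deposited and none was called after length correction. Each of these 3 calls was also lost without either control, dap 2, dapCRL4 1 or either dapPCNA library, those of ple and Shab without dapCRL4 2 and that of Shab without dap 1, with an adjusted p of up to 0.249. All 3 were lost without a filter and without a mean-variance trend, and those of futsch and ple when only the groups compared were fitted.

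Other lists were called with a higher adjusted p in dap. Stress and heat-shock genes had a median of −0.51 over 23 genes (camera adjusted p = 0.0126; adjusted p = 0.773 with an estimated correlation), with 1 member higher and 2 lower, or 2 higher and 4 lower when adjusted over the list alone. Its median was −0.28 without control 1 (0.0492). Its adjusted p was 0.0542 without dap 2, and 0.0950 without a filter, where the median was −0.29. Salivary gland and tracheal genes had a median of −0.20 over 13 genes (camera adjusted p = 0.0126, and 0.773 with an estimated correlation), with 1 higher and 2 lower, or 1 higher and 5 lower when adjusted over the list alone. Their adjusted p was 0.237 after length correction. Neural patterning genes had a median of −0.10 over 31 genes (camera adjusted p = 0.0133, and 0.773 with an estimated correlation), with 3 lower over all genes and 1 lower adjusted over the list alone. They were not called without control 2 (0.0574), without dap 2 (0.258) or after length correction (0.925), and had a median of −0.16 without dap 1. Lists not called in dap included mitosis, with a median of −0.04 over 47 genes (adjusted p = 0.117), and muscle, with −0.03 over 28 genes (adjusted p = 0.0611). Muscle was called lower without control 1 (median −0.12, 0.000886), without dap 2 (−0.10, 0.00126) and under quantile normalization (−0.14, 0.00421). Members of the mitosis list called in dap included Mis12, a kinetochore gene (log2 −1.05, limma adjusted p = 0.0243). The call of Mis12 was lost without control 1, control 2 or dap 2, and without a filter (0.0778). The centrosomal gene cnn fell by 0.39 as deposited and was at −0.11 after length correction, where it was not called.

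The number of genes called in dap moved when single libraries were left out, including libraries outside the comparison. It was 193 without control 1, 68 without control 2 and 73 without dap 2. It was 768 and 779 without dapCRL4 1 and 2, 685 and 693 without dapPCNA 1 and 2, and 2225 and 2214 without dapCDI 1 and 2. The higher share of the calls was 72.3%, or 56.5% under quantile normalization. Without dap 1 it was 44.7% of 956 calls, so that most were then lower. After length correction 380 genes were called, 306 of them also called as deposited.

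The CRL4 form was compared with the control, where the name in the labels points to Cullin 4 ubiquitin ligase, which targets proteins through a PIP degron. In dapCRL4, 107 genes rose and 44 fell, 10245 were not called, and 58 of the calls were at least 2-fold. CG31219 rose 14.0-fold (log2 3.80, SE 0.11, limma adjusted p = 2.28e-07), y rose 17.1-fold to 2.60 ± 0.125 RPKM, and CG34437 (3R, 28283719 to 28284725) rose 6.64-fold from 2.37 ± 0.0676 to 15.8 ± 0.00394 RPKM (SD, n = 2; log2 2.73, adjusted p = 3.7e-05). CG14985 fell 3.19-fold (log2 −1.67, adjusted p = 0.000529), PH4alphaSG2 fell 2.48-fold (log2 −1.31, adjusted p = 0.000114), and MtnA rose 1.93-fold (adjusted p = 0.00131). CG11700 and CG8100 fell by 2.84 and 2.06 log2, with an adjusted p of 0.0501 without control 1 for CG11700 and 0.0588 without control 2 for CG8100. Mis12 (3L, 6968035 to 6969048) fell 2.96-fold (log2 −1.57, adjusted p = 0.00878), and was not called without control 1, control 2 or dapCRL4 2, with an adjusted p of up to 0.0865.

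Mitosis and chromosome segregation genes fell as a list in dapCRL4, with a median of −0.36 (camera adjusted p = 9.39e-17; adjusted p = 0.302 with an estimated correlation). Over all genes 5 members were called lower, and 20 when adjusted over the list alone. The cytokinesis kinesin pav (3L, 4242734 to 4246233) fell 1.96-fold from 4.41 ± 0.145 to 2.25 ± 0.166 RPKM (log2 −0.97, limma adjusted p = 0.0152). Topoisomerase gene Top2 (2L, 19447365 to 19453490) fell from 30.9 ± 2.28 to 20.8 ± 0.911 RPKM (log2 −0.57, adjusted p = 0.0130). The neuronal differentiation factor nerfin-1, of the neuroblast list (3L, 909112 to 912319) fell from 30.4 ± 0.324 to 18.9 ± 1.58 RPKM (log2 −0.69, adjusted p = 0.0132). These 3 calls were lost with some single libraries left out, which also leaves fewer samples. That of pav was lost without either control or either dapCRL4 library (up to 0.136), that of Top2 without control 1 or either dapCRL4 library (up to 0.138), and that of nerfin-1 without either control or dapCRL4 2 (up to 0.139). With only the groups compared in the fit pav was at 0.0616 and Top2 at 0.0516, and without a filter nerfin-1 was at 0.0773.

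The other list calls in dapCRL4 depended on the libraries kept, length, the filter or the normalization. Muscle genes had a median of 0.15 (camera adjusted p = 0.0113, and 0.829 with an estimated correlation), with 1 member higher, or 4 adjusted over the list alone. The muscle call was lost without control 1 (0.562) and without dapCRL4 2 (0.0792), and its median was 0.22 without control 2. Stress genes had a median of −0.47 (camera adjusted p = 0.0113, and 0.829 with an estimated correlation), with 1 higher, or 3 higher and 3 lower adjusted over the list alone. The stress call was lost without control 1 (0.0969) and without dapCRL4 2 (0.580). Cyclins and S-phase entry genes had a median of −0.12 over 25 genes (camera adjusted p = 0.0113, and 0.765 with an estimated correlation; 0.0693 without dapCRL4 2), and −0.04 without control 1. Neuronal, salivary gland and neuroblast lists had medians of −0.12, −0.11 and −0.09, with camera adjusted p of 0.0299, 0.0389 and 0.0256 and 0.829 each with an estimated correlation. None of these 3 lists was called after length correction, where the adjusted p was 0.476, 0.237 and 0.0738. Over all genes 1 salivary gland and 1 neuroblast gene were lower, and adjusted over the list alone 1 of each was lower and 1 neuroblast gene higher, with 1 cyclin gene lower. As deposited the neuronal call was lost without control 1 (0.123) and dapCRL4 2 (0.854), and its median was −0.18 without dapCRL4 1. The neuroblast call was lost without control 2 (0.0648) and dapCRL4 2 (0.0792), and the salivary gland call without control 2 (0.174), dap 1 (0.0503), dap 2 (0.0508) and dapCRL4 2 (0.169). Without a filter the neuroblast, neuronal and salivary gland lists were at 0.118 each and the stress list at 0.143 with a median of −0.16. Under quantile normalization the adjusted p was 0.0575 for neuroblast, neuronal and stress lists and 0.0686 for salivary gland. Neuronal and salivary gland lists were at 0.0501 and 0.0554 with centred libraries and at 0.0674 each without a mean-variance trend, and salivary gland at 0.0594 with only the groups compared in the fit. The replication list had a median of 0.09 and was not called (adjusted p = 0.269), except without control 1 (0.0260). The count of changed genes was 66 and 55 without control 1 and 2, 65 and 55 without dapCRL4 1 and 2, and 293 and 297 without dapCDI 1 and 2.

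The PCNA form was compared with the control, since PIP degrons act when their protein is bound to the sliding clamp PCNA. In dapPCNA, 77 genes rose and 58 fell, 10261 were not called, and 52 of the calls were at least 2-fold. CG8539 rose 16.9-fold (log2 4.08, limma adjusted p = 5.03e-05), y rose 16.5-fold (adjusted p = 0.000137) and CG31219 rose 13.9-fold (adjusted p = 2.29e-07). BobA, a gene of the Bearded family, rose 6.76-fold from 0.840 ± 0.229 to 5.59 ± 0.543 RPKM (SD, n = 2; adjusted p = 0.00337, and 0.0644 without a filter). CG42822 (3R, 17413901 to 17414607) fell 2.52-fold from 105 ± 5.41 to 41.7 ± 4.27 RPKM (log2 −1.33, adjusted p = 0.000244), and PH4alphaSG2 fell 2.23-fold (adjusted p = 0.000298). The nerfin-1 transcript fell 1.76-fold to 17.3 ± 0.454 RPKM (log2 −0.81, SE 0.11, adjusted p = 0.00443), a call that held in every setting.

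By median, mitosis genes fell furthest as a list in dapPCNA, at −0.49 (camera adjusted p = 1.13e-22; adjusted p = 0.165 with an estimated correlation). The list was not called between dapPCNA and dapCRL4 or dapCDI (camera adjusted p = 0.147 and 0.260). Against the control 8 members were called lower over all genes, and 29 of 47 when adjusted over the list alone. Top2 fell 1.68-fold to 18.4 ± 0.0258 RPKM (log2 −0.74, SE 0.09, limma adjusted p = 0.00245), and the citron kinase gene sti (3L, 12507998 to 12514815), which was not in the list and overlaps a long non-coding gene, fell 2.28-fold from 6.03 ± 0.182 to 2.64 ± 0.0599 RPKM (log2 −1.19, adjusted p = 0.00297). The calls of Top2 and sti held in every setting and with any library left out. The condensin gene CAP-D2 fell by 1.13 log2 (adjusted p = 0.00502, and 0.0692 without control 1). Mis12 fell by 1.71 (adjusted p = 0.00438), a call lost without control 1. Mis12 was also called lower in dap, and it was not called in dapPCNA against dap (limma adjusted p = 0.134). The mitotic kinesin Klp67A, also outside the list, which overlaps CG34456, fell by 1.19 (adjusted p = 0.0161), and its call was lost without either control or either dapPCNA library, with an adjusted p of up to 0.143. Cyclins and S-phase entry genes fell with a median of −0.17 (camera adjusted p = 8.53e-06; adjusted p = 0.317 with an estimated correlation), with 1 lower over all genes and 7 adjusted over the list alone. That member, CycA (3L, 11826719 to 11833578), fell from 36.0 ± 3.20 to 24.8 ± 1.79 RPKM (adjusted p = 0.0179), and was not called without control 1, dapPCNA 1 or dapPCNA 2, with an adjusted p of up to 0.155. That call was also lost without a filter, without a mean-variance trend and with only the groups compared in the fit.

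Muscle genes rose slightly in dapPCNA, with a median of 0.15 (camera adjusted p = 0.000228; adjusted p = 0.897 with an estimated correlation), none over all genes and 1 adjusted over the list alone. Without control 1 the adjusted p of the muscle list was 0.254. Replication, neuronal and stress lists had medians of 0.05, −0.05 and 0.08 and were not called, with adjusted p of 0.782, 0.332 and 0.795. The neuronal list was called lower with only the groups compared in the fit (0.0286). The count of changed genes was 78 and 71 without control 1 and 2, and 75 and 72 without dapPCNA 1 and 2.

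The CDI form was compared with the control as the remaining stabilized form, and the labels do not spell out its name. In dapCDI, 492 genes rose and 294 fell, 9610 were not called, and 80 of the calls were at least 2-fold. Besides dap itself, y rose 21.4-fold to 3.26 ± 0.0237 RPKM (log2 4.42, limma adjusted p = 6.28e-05), CG8539 rose 18.7-fold (adjusted p = 2.28e-05) and CG31219 rose 13.2-fold (adjusted p = 2.77e-07). CG11700 fell 11.3-fold (log2 −3.50, adjusted p = 0.000891) and CG8100 fell 6.84-fold (log2 −2.77, adjusted p = 0.000716). The small nucleolar RNA gene snoRNA,Me28S-U2134b was listed at 1.01 and 0.514 RPKM in the control and at 0 in both dapCDI libraries, a call lost with log2(RPKM + 1) and with only the groups compared in the fit. Psf1 rose 1.82-fold (adjusted p = 0.0228), a call lost without either control or dapCDI 1, with an adjusted p of up to 0.140, and without a filter, without a mean-variance trend or with only the groups compared. Adh, the alcohol dehydrogenase gene that overlaps Adhr, rose from 419 ± 31.4 to 698 ± 95.9 RPKM (adjusted p = 0.00521, and 0.0517 without control 2), a call lost without a filter and with only the groups compared.

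Mitosis genes fell in dapCDI with a median of −0.37 (camera adjusted p = 2.16e-10; adjusted p = 0.722 with an estimated correlation), 9 members over all genes and 18 adjusted over the list alone. Top2 fell 1.63-fold to 18.9 ± 0.626 RPKM (limma adjusted p = 0.00332), pav fell by 0.85 log2 (adjusted p = 0.0235) and cnn fell by 0.41 (−0.15 and not called after length correction). The calls of pav and cnn were lost without either control or dapCDI 1, with an adjusted p of up to 0.128 and 0.135, and that of cnn without a mean-variance trend. When only the 2 groups were fitted the calls of Top2 (0.0806), pav and cnn were lost. Muscle genes rose with a median of 0.28 (camera adjusted p = 0.000202; adjusted p = 0.754 with an estimated correlation), 6 members over all genes and, adjusted over the list alone, 15 higher and 2 lower, and the median was 0.18 without control 1. The muscle LIM protein gene Mlp60A (2R, 24074602 to 24078223) rose 1.62-fold (log2 0.70, SE 0.10, limma adjusted p = 0.00831), and its call was lost without control 1 or dapCDI 1 (up to 0.0807), without a filter and with only the groups compared. Neuronal genes fell with a median of −0.35 (camera adjusted p = 2.37e-07; adjusted p = 0.754 with an estimated correlation), 4 over all genes and 12 adjusted over the list alone. After length correction that median was −0.10 (adjusted p = 0.00883). The fall rested largely on dapCDI 1, and was −0.19 without it (0.00456). The list median deviated from the mean of all libraries by −0.34 in dapCDI 1 and −0.04 in dapCDI 2, and after length correction by −0.14 and −0.00924. The neuronal RNA-binding gene elav fell by 0.83 as deposited and was at −0.44 after length correction (adjusted p = 0.0739), while acetylcholinesterase gene Ace fell by 1.07 and by 0.73 (adjusted p = 0.0343 and 0.0454). As deposited both calls were lost without either control, either dapPCNA library or dapCDI 1, and that of elav also without either dapCRL4 library, with an adjusted p of up to 0.187 for Ace and 0.261 for elav. Both were also lost without a filter, without a mean-variance trend and with only the groups compared.

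Cyclins, neuroblast factors and neural patterning genes moved little in dapCDI. Their medians were −0.09, −0.07 and −0.14, with camera adjusted p of 0.0196, 0.0263 and 0.0259 and, with an estimated correlation, adjusted p = 0.754, 0.774 and 0.774. Over all genes 3 cyclin genes were lower, 6 neuroblast factors were lower, and 1 patterning gene was higher and 3 lower. Adjusted over the list alone there were 3 lower among the cyclins, 2 higher and 10 lower among neuroblast factors, and 2 higher and 5 lower among patterning genes. Without dapCDI 2 the cyclin list was at 0.0518, and without dapCDI 1 its median was −0.15. The neuroblast list was at 0.0926 without control 2, at 0.0797 without dapCDI 1 and at 0.114 after length correction. The patterning list was at 0.122 without control 2, at 0.171 without dapCDI 1 and at 0.870 after length correction. Without dapCDI 2 the patterning median was −0.09. Neuroblast and patterning lists were also lost without a filter (0.0908 and 0.0780) and under quantile normalization (0.0738 each). Replication, stress and salivary gland lists had medians of 0.14, 0.08 and −0.12 and were not called, with adjusted p of 0.159, 0.792 and 0.0679. Replication was called higher without control 1 (0.0121) and without dapCDI 2 (0.00889), and salivary gland lower without control 1 (0.0137). The count of changed genes was 78 and 95 without control 1 and 2, 83 and 2595 without dapCDI 1 and 2, 245 and 261 without dapCRL4 1 and 2, and 223 and 226 without dapPCNA 1 and 2. After length correction 311 genes were called, 254 of them also called as deposited.

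The stabilized forms were compared with wild-type dacapo to find what stabilization adds. The level of dap RNA also differed from that in dap, by 0.95 log2 in dapCDI. It differed by −0.11 in dapCRL4 and −0.23 in dapPCNA, where it was not called. Strains are not described further, so an effect of stabilization cannot be told apart from transgene level or strain background. For the mean of the 3 stabilized forms against dap, 31 genes rose and 43 fell, 10322 were not called, and 8 of the calls were at least 2-fold. The higher share was 41.9%, but 14 of 20 calls were higher without dap 1, 4 of 5 without dap 2 and 56.4% without a filter, 51.6% of 93 with libraries centred on their medians and 47.7% of 132 under quantile normalization. The Aurora B kinase gene ial (2L, 10856797 to 10858094) fell by 1.04 log2 (SE 0.14, limma adjusted p = 0.0183), pav by 0.94 (adjusted p = 0.0186), CAP-D2 by 0.88 (adjusted p = 0.0186) and sti by 0.85 (adjusted p = 0.0189). The call of ial was lost without dap 2 or dapCRL4 1, and those of the other 3 without dap 1, dap 2 or dapCRL4 1. The highest adjusted p with a library left out was 0.127 for ial, 0.122 for pav, 0.152 for CAP-D2 and 0.0811 for sti. The call of ial was also lost without a filter and without a mean-variance trend, and sti was at 0.0517 with only the groups compared. CG33128 rose by 1.76 log2 (SE 0.20, adjusted p = 0.0103), and was at 0.0517 without dap 2.

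As a list, mitosis genes were lower in the stabilized forms than in dap, with a median of −0.36 (camera adjusted p = 2.04e-11; adjusted p = 0.305 with an estimated correlation), 5 lower over all genes and 26 adjusted over the list alone. DNA replication genes were lower with a median of −0.19 (camera adjusted p = 2.34e-08, and 0.551 with an estimated correlation), none over all genes and 6 adjusted over the list alone. Muscle genes were higher with a median of 0.22 (camera adjusted p = 5.79e-13, and 0.305 with an estimated correlation), 3 over all genes and 12 adjusted over the list alone. Stress genes were higher with a median of 0.39 (camera adjusted p = 0.000225, and 0.551 with an estimated correlation), with none called either way. The stress median deviated from the mean of all libraries by −0.11 in dap 1 and by −0.90 in dap 2, and the difference was 0.16 without dap 2 (0.0260) and 0.82 without dap 1. Cyclins and S-phase entry genes were lower with a median of −0.11 (camera adjusted p = 0.00922, and 0.551 with an estimated correlation), 2 over all genes and 7 adjusted over the list alone, and were at 0.132 without dap 1. Hemocyte and basement membrane genes had a median of 0.16 over 12 genes (camera adjusted p = 0.00173, and 0.293 with an estimated correlation), none over all genes and, adjusted over the list alone, 6 higher and 1 lower. Their adjusted p was 0.0538 after length correction and 0.0836 without dap 1. Neuronal genes had a median of 0.20 (camera adjusted p = 1.56e-05, and 0.602 with an estimated correlation), but 0.03 and not called after length correction, −0.05 without dap 2 (0.198) and 0.37 without dap 1. The count of changed genes was 35 and 35 without control 1 and 2, 20 and 5 without dap 1 and 2, 547 without dapCDI 1, 13 and 40 without dapCRL4 1 and 2, and 28 and 37 without dapPCNA 1 and 2.

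**Figure D3:**
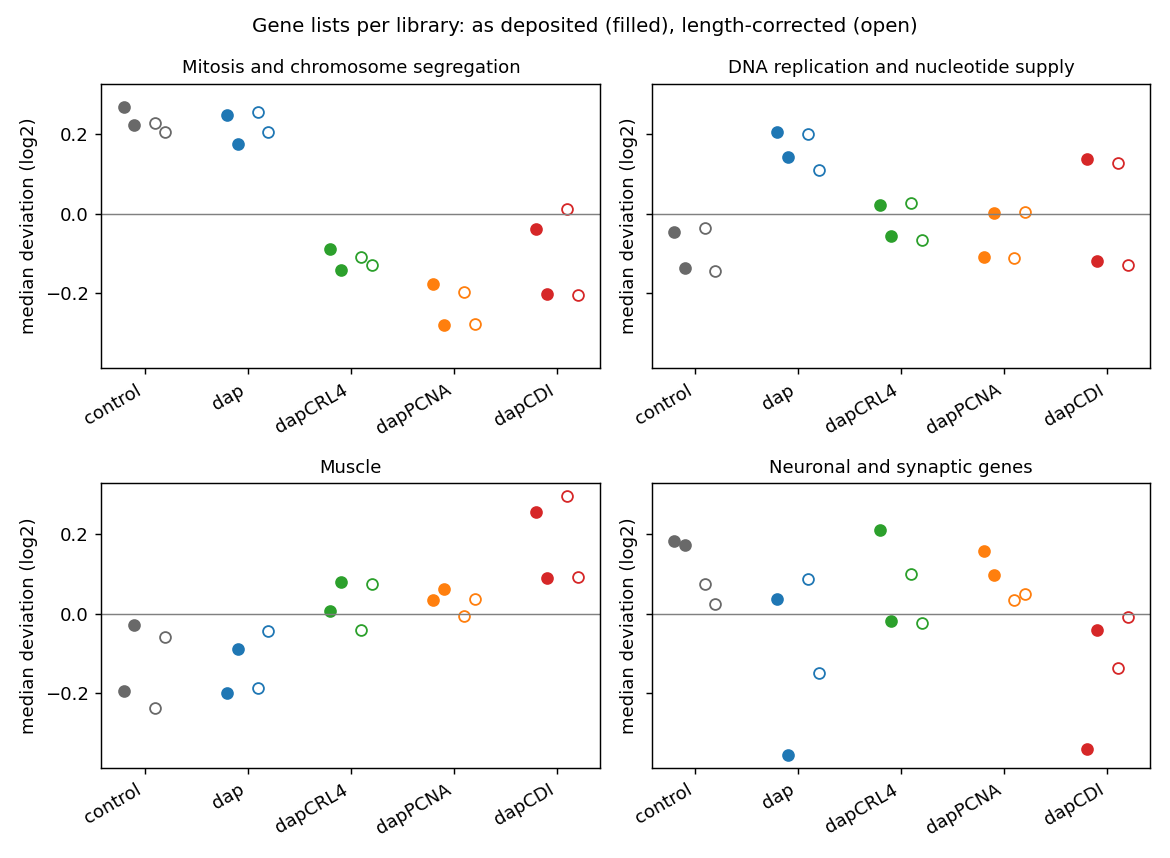
Median deviation from the mean of the 10 libraries (vertical axes, log2 RPKM) of the mitosis, DNA replication, muscle and neuronal lists in each library, by genotype (horizontal axes), with filled points as deposited and open points after length correction. As deposited, the mitosis medians lie between 0.18 and 0.27 in control and dap and between −0.28 and −0.04 in the 3 stabilized forms.

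Each stabilized form was also set against wild-type dacapo alone. In dapPCNA, 36 genes rose and 102 fell, with 10258 not called. The cytochrome P450 gene Cyp4p2 (2R, 9237512 to 9239831) rose from 9.49 and 11.1 RPKM in dap to 30.7 and 32.4 RPKM (log2 1.62, SE 0.11, limma adjusted p = 0.000581), and CG30148 fell from 22.5 and 21.5 to 4.11 and 2.72 RPKM (log2 −2.72, adjusted p = 0.000715). These calls held in every setting. The higher share was 26.1%, against 38.6% under quantile normalization and 39.4% with libraries centred on their medians, and turned over to 70.1% of 67 calls without dap 1. In dapCRL4, 5 genes rose and 12 fell, with 10379 not called. Synaptotagmin gene Syt7 rose by 0.70 log2 (adjusted p = 0.0227) and glutathione transferase gene GstE9 fell by 1.11 (adjusted p = 0.0227). Both calls were lost without dap 2 or dapCRL4 1, that of Syt7 also without dapCRL4 2 and that of GstE9 also without dap 1, with an adjusted p of up to 0.173. With only the 2 groups in the fit they were at 0.101 and 0.107. Most calls turned higher without dap 1 (10 of 16), without dap 2 (2 of 3) and without a filter (37 of 66). In dapCDI, 6 genes rose and 9 fell, with 10381 not called. Here dap rose by 0.95 log2 (adjusted p = 0.000975), a call lost only when just the 2 groups were fitted (0.0825), and the Notch target Hey fell by 0.73, a call lost without any 1 of the 10 libraries (up to 0.173), with the stricter filter, with centred libraries and with only the groups compared. Here calls were mostly higher without dap 1 (8 of 8), without dap 2 (3 of 4) and without a filter (20 of 39), and the 1 call left without control 1, without dapPCNA 2 or with only the groups compared was higher.

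Mitosis genes were lower than in dap in each stabilized form, with medians of −0.35 in dapCRL4, −0.43 in dapPCNA and −0.30 in dapCDI (camera adjusted p = 8.3e-09, 4.54e-08 and 1.42e-11; adjusted p = 0.474, 0.507 and 0.209 with an estimated correlation). Members called over all genes were 6 lower in dapPCNA and none in dapCRL4 or dapCDI, and adjusted over the list alone 16, 25 and 8 were lower in dapCRL4, dapPCNA and dapCDI, with 1 higher in dapCRL4. The mitosis median in dapCDI was −0.19 without dapCDI 2. Replication genes had medians of −0.18, −0.26 and −0.16 in the same order (6.63e-07, 8.39e-07 and 1.64e-06; 0.768, 0.507 and 0.827 with an estimated correlation), and the last was at 0.239 without dapCDI 2 and had a median of −0.28 without dapCDI 1. No replication gene was called over all genes, and adjusted over the list alone 5 were lower in dapPCNA and none in the other 2 forms. Muscle genes had medians of 0.16, 0.17 and 0.31 (8.98e-08, 1.49e-07 and 9.78e-20; 0.681, 0.507 and 0.209 with an estimated correlation). Over all genes 1, 2 and 0 muscle genes were called higher, and 7, 9 and 18 adjusted over the list alone. Stress genes had medians of 0.62 in dapPCNA and 0.52 in dapCDI (camera adjusted p = 0.000323 and 3.94e-07; 0.507 and 0.554 with an estimated correlation), and 0.11 in dapCRL4 without a call (0.491). Without dap 2 these were 0.42 (0.00860), 0.29 (0.000509) and −0.18 (0.912), and without dapCRL4 2 the dapCRL4 list was called at 0.35 (0.00327). In dapCDI the stress median was 1.02 without dap 1, 0.23 without dapCDI 1 and 0.82 without dapCDI 2. Neuronal genes had medians of 0.30 in dapCRL4 and 0.33 in dapPCNA (6.63e-07 and 1.42e-07; 0.768 and 0.507 with an estimated correlation), which became 0.11 and 0.09 after length correction (0.0621 and 0.0123). Without dap 2 they were 0.05 and 0.15 (0.0157 and 0.000753), and without dapCRL4 1 that in dapCRL4 was 0.19 (0.00522). In dapCDI the neuronal median was −0.06 without a call (0.805). It was called lower without dap 2 (−0.22, 0.0190) and without dapCDI 2 (−0.17, 0.00102), but higher without dap 1 (0.09, 0.00615) and without dapCDI 1 (0.14, 3.19e-05). No stress or neuronal gene was called in these comparisons over all genes or adjusted over the list alone.

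Remaining list calls against dap were small. Hemocyte genes had medians of 0.13, 0.14 and 0.19 in dapCRL4, dapPCNA and dapCDI (camera adjusted p = 0.0150, 0.0215 and 0.000332; 0.474, 0.507 and 0.179 with an estimated correlation), the last at 0.0534 without dapCDI 2. The calls in dapCRL4 and dapPCNA were lost after length correction (0.289 and 0.360), without dap 1 (0.229 and 0.140) and without a filter (0.106 and 0.0835), and that in dapPCNA also without dapPCNA 2 (0.0664). Cyclins had −0.17 in dapPCNA and −0.11 in dapCDI (0.0104 and 0.00683; 0.507 and 0.554 with an estimated correlation), at 0.0836 and 0.109 without dap 1 and 0.0771 in dapCDI without dapCDI 1. Fat body genes had 0.12 over 9 genes in dapPCNA (0.0452, and 0.507 with an estimated correlation), at 0.0508 without either control and 0.370 without dap 1, at −0.04 without dapPCNA 2 (0.123) and at 0.0686 after length correction, and lost without a filter, with the stricter filter, with centred libraries, without a mean-variance trend and with only the groups compared. Cyclins in dapCRL4 were called after length correction (−0.13, 0.0116), without dap 2 (−0.13, 0.0314) and without dapCRL4 1 (−0.12, 0.0214). The cyclin median in dapCDI was −0.17 without dap 2, and the fat body median in dapPCNA was 0.19 without dap 2 and 0.36 without dapPCNA 1. With the stricter filter patterning genes were called higher in dapCRL4 (0.0282) and dapPCNA (0.0281) and salivary gland in dapPCNA (0.0485). Adjusted over the list alone, 3 hemocyte genes were higher in dapCRL4 and 3 higher and 1 lower in dapPCNA, 3 fat body genes were higher in dapPCNA, and 9 cyclin genes were lower and 1 higher in dapPCNA with 1 lower in dapCDI. Counts of changed genes moved when single libraries were left out. Without control 1 and 2 they were 51 and 41 in dapPCNA, 7 and 7 in dapCRL4, and 1 and 2 in dapCDI. Without dap 1 and 2 they were 67 and 18 in dapPCNA, 16 and 3 in dapCRL4, and 8 and 4 in dapCDI. Without dapCDI 1 and 2 they were 725 and 741 in dapPCNA, 42 and 64 in dapCRL4, and 13 and 37 in dapCDI. Without dapCRL4 1 and 2 they were 46 and 53 in dapPCNA, 1 and 6 in dapCRL4, and 2 and 2 in dapCDI. Without dapPCNA 1 and 2 they were 8 and 25 in dapPCNA, 4 and 3 in dapCRL4, and 2 and 1 in dapCDI.

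The 3 stabilized forms were compared with each other to see whether the 3 alterations differ in effect. Here too an effect of the alteration cannot be told apart from transgene level or strain background. A total of 14 genes differed among them by limma's moderated F test, 10382 were not called, and 1269 passed at an unadjusted p under 0.05. The dap transcript differed most (adjusted p = 0.000201), being higher in dapCDI than in dapPCNA by 1.18 log2 (adjusted p = 0.000125) and than in dapCRL4 by 1.06 (adjusted p = 0.000346). CG30148 came next (adjusted p = 0.000498). Its level did not follow stabilization, at 2.59 and 1.90 RPKM in the control and 4.11 and 2.72 in dapPCNA. It stood at 22.5 and 21.5 RPKM in wild-type dap, 26.6 and 27.6 in dapCRL4, and 22.7 and 18.2 in dapCDI. The gene CG18661 (2L, 8997605 to 8998544; adjusted p = 0.00788) stood at 4.07 and 3.95 RPKM in dapPCNA against 9.46 and 9.08 in dapCRL4 and 9.31 and 9.46 in dapCDI. CG18278 (2R, 13408042 to 13409887; adjusted p = 0.0153), which overlaps BaraA2, stood at 5.18 and 4.71 RPKM in dapCDI, 2.45 and 1.92 in dapCRL4, and 1.36 and 1.60 in dapPCNA. Pairwise, 6 genes were called between dapCRL4 and dapPCNA, 18 between dapCDI and dapPCNA and 7 between dapCDI and dapCRL4. The count of 14 was 6 without dap 1, 9 without dap 2, 9 without dapCRL4 1, 9 without dapPCNA 1 and 230 without dapCDI 2.

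List differences between stabilized forms were lost with certain single libraries left out, and some also under other processing. Stress genes were lower in dapCRL4 than in dapPCNA with a median of −0.58 (camera adjusted p = 6.23e-06; adjusted p = 0.590 with an estimated correlation) and higher in dapCDI than in dapCRL4 with 0.48 (0.000359, and 0.973 with an estimated correlation). Their median deviation was 0.07 in dapCRL4 1 and −0.66 in dapCRL4 2. Without dapCRL4 2 these calls were lost (0.0848 and 0.430), the latter also without dapCDI 1 (0.257). The medians were −0.95 and 0.84 without dapCRL4 1, the former was −0.39 without dapPCNA 2 and the latter 0.78 without dapCDI 2. Neuronal genes were lower in dapCDI than in dapPCNA with a median of −0.34 (3.69e-08, and 0.842 with an estimated correlation) and than in dapCRL4 with −0.29 (1.89e-06, and 0.973 with an estimated correlation), both lost without dapCDI 1 (0.115 and 0.742), the latter at −0.17 without dapCRL4 1. After length correction these medians were −0.14 and −0.12 (0.00163 and 0.0152). Muscle genes were higher in dapCDI than in dapCRL4 with a median of 0.17 (0.0131, and 0.973 with an estimated correlation), lost without dapCRL4 1 (0.197), without dapCDI 1 (0.388) and under quantile normalization (0.491). In dapCRL4 against dapPCNA, cuticle, neuropeptide and cyclin lists had medians of −0.04, −0.09 and 0.09 (0.0154, 0.0154 and 0.0310; 0.590 each with an estimated correlation). All 3 were lost without dapPCNA 2 (0.145, 0.125 and 0.178), cuticle and cyclins also without dapCRL4 1 (0.137 and 0.307), neuropeptides without dapCRL4 2 (0.397) and cyclins after length correction (0.0639). Under quantile normalization the cuticle, neuropeptide and cyclin lists were lost too (camera adjusted p = 0.160, 0.0594 and 0.104). Cuticle was also lost without a filter (0.0781), cyclins with the stricter filter (0.146) and neuropeptides with centred libraries (0.0659). The neuropeptide median was −0.18 without dapCRL4 1 and −0.23 without dapPCNA 1, that of cuticle −0.06 without dapPCNA 1 and that of cyclins 0.15 without dapCRL4 2. The mean of the cuticle list was above 0. No member of these lists was called in these comparisons over all genes or adjusted over the list alone.

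Changes against the control were compared across the 4 forms to find those common to all. A set of 64 genes was called in all 4 forms, 49 higher and 15 lower, and 58 of them were also called in all 4 after length correction. It included CG31219, CG8539, y, p24-2, MtnA, CG11700, CG8100, PH4alphaSG2 and Mis12. Independent lists of these sizes would share 0.0032 higher and 0.000227 lower genes, and in 100 simulations with the shared controls but no change the highest number was 0. For these genes the largest and smallest of the 4 changes differed by a median of 0.28 log2. Of the 64, 47 lay on the third chromosome (73.4%), which holds 44.1% of the genes tested (Fisher's exact test, odds ratio 3.53, two-sided p = 2.91e-06). The test treats genes as independent, but some are neighbours, such as CG6912 and CG3984, or overlap, such as p24-2 and Unc-115b. Its p-value may therefore be too small. Among 1541 genes called in 1 to 3 forms the share on the third chromosome was 45.9%. Arms 2L, 2R, 3L, 3R and X held 6, 7, 15, 32 and 4 of the 64 genes. The number called in all 4 forms was 43 without control 1 and 39 without control 2, with 34 and 32 of the 64 among them.

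**Figure D4:**
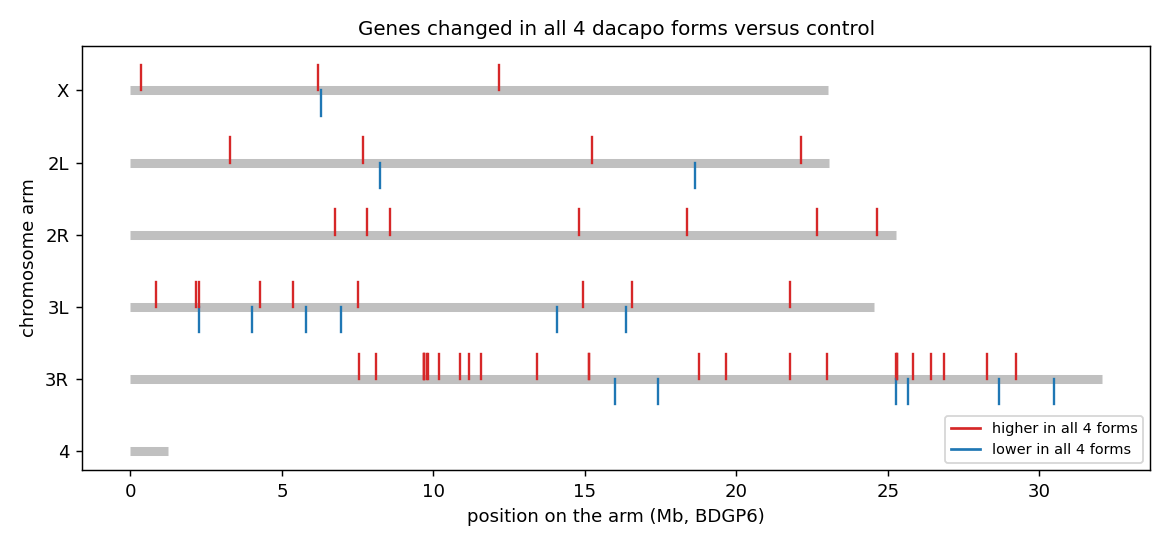
Positions (horizontal axis, megabases) of the 64 genes called in all 4 forms against the control on the chromosome arms (vertical axis), with red marks for the 49 higher and blue marks for the 15 lower genes. Arms 3L and 3R hold 15 and 32 of them.

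Since the 4 comparisons share 2 control libraries, their changes are correlated even without an effect. Across genes, Pearson's r between the changes in dap and dapCDI was 0.656 against 0.508 in simulations without a change, with a covariance of 0.218 against 0.162, and 448 genes were called in both. Independent lists would share 42.0 higher and 9.62 lower genes. For dap and dapCRL4 r was 0.628 against 0.514, with a covariance of 0.188 against 0.165 and 109 shared calls against 9.13 higher and 1.44 lower. For dap and dapPCNA r was 0.601 against 0.539, with 0.185 against 0.173 and 80 shared calls against 6.57 and 1.90. For dapCRL4 and dapPCNA r was 0.617 against 0.489, with 0.188 against 0.159 and 87 shared calls against 0.793 and 0.245. For dapCRL4 and dapCDI r was 0.644 against 0.478, with 0.211 against 0.153 and 117 shared calls against 5.06 and 1.24. For dapPCNA and dapCDI r was 0.614 against 0.525, with 0.207 against 0.168 and 105 shared calls against 3.64 and 1.64. In the order given, the simulations shared a mean of 0.03, 0.03, 0.03, 0.04, 0.03 and 0.01 calls, and after length correction 150, 124, 88, 109, 128 and 105 calls were shared. Part of the excess of shared calls over independent lists may come from the shared control libraries. The independent lists leave these out, while the simulations leave out any effect.

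Of the 160 list tests, 47 were called with the preset correlation and none with an estimated correlation, where the lowest adjusted p was 0.165 and 13 tests had an unadjusted p under 0.05. Apoptosis, Cullin ligase, cuticle, DNA damage, germ cell, glia, gut, neuropeptide and transgene marker lists were not called in any of the 8 comparisons in the fit of all 10 libraries as deposited, with the filter at 1 RPKM. Glia were called lower in dapCDI against the control without control 1 (0.0374) and without dapCDI 2 (0.0156), and transgene markers higher in dapCRL4 without control 2 (0.0296). After length correction cuticle and neuropeptide lists were called higher in dapPCNA against dap (0.0230 and 0.0196), as were germ cells with the stricter filter (median 0.20, 0.0364). In dap against control their medians were 0.04 (16 genes), −0.01 (21), 0.08 (44), 0.03 (23), −0.05 (11), −0.10 (20), 0.05 (12), 0.06 (23) and 0.14 (7), with camera adjusted p of 0.997, 0.954, 0.997, 0.306, 0.306, 0.275, 0.997, 0.617 and 0.306. The yellow gene was the only member of the transgene marker list called in that comparison. In that comparison the median, mean and test of the apoptosis, Cullin ligase, cuticle, cyclin, DNA damage, gut and neuropeptide lists differed in sign. The same held for hemocytes in dapCRL4, dapPCNA and dapCDI against the control, for apoptosis in dapCRL4 and dapCDI, for Cullin ligase, cuticle, fat body and germ cells in dapCRL4, for glia in dapPCNA, and for DNA damage and gut in dapCDI. Against dap it held in 1 or more stabilized forms or their mean for apoptosis, cuticle, DNA damage, germ cells, glia, gut, neuroblast factors, neuronal genes, neuropeptides, salivary gland and neural patterning, always where the list was not called.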

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

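All tests of explanations here were chosen after the results they concern had been seen, while the comparisons between genotypes were fixed beforehand.

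Several genes drew attention because they differed between stabilized forms or between a stabilized form and wild-type dacapo. The dap transcript was higher in dapCDI than in dap by 0.95 log2, than in dapPCNA by 1.18 and than in dapCRL4 by 1.06 (limma, n = 2 per genotype, with both dapCDI libraries above all others). Among the 3 stabilized forms, limma's adjusted p of the F test was 0.000498 for CG30148, 0.00788 for CG18661 and 0.0153 for CG18278. It was 0.00788 for snoRNA,Me28S-U2134b, listed at 0 in both dapCDI libraries, and 0.0295 for snoRNA,lola-d, listed at 0 in both dapCRL4 libraries. Transcripts this short and low carry few reads, and polyA selection recovers small nucleolar RNAs poorly.

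Lists drew attention where the mean of the stabilized forms differed from dap. The medians were −0.36 for mitosis, −0.19 for DNA replication, −0.11 for cyclins and S-phase entry, 0.22 for muscle and 0.39 for stress genes. None of these passed with an estimated correlation, and the stress median was 0.16 without dap 2.

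The 64 genes changed in all 4 dacapo forms against the control formed the first pattern weighed. Chance overlap of comparisons that share 2 control libraries gave at most 0 such genes in 100 simulations. The simulations held no change, and pairs of comparisons there shared a mean of only 0.01 to 0.04 calls. A count of 0 therefore cannot decide how many joint calls the shared controls add where many genes are called. The concentration of the 64 genes on the third chromosome (odds ratio 3.53) is what a chromosome 3 carried by the dacapo lines and not by the control line would give, so strain background may explain part of the set. Raised dacapo stays open, because the size of the change in dapCDI minus that in dapPCNA had a median of 0.0266 (95% bootstrap interval over genes −0.05 to 0.06), although dap RNA differed by 1.18 log2, and stabilized protein need not follow RNA. The only member of the transgene marker list in the set was y. That gene stood at 0.119 and 0.195 RPKM in the control and at 1.91 to 3.28 RPKM in the dacapo forms. For the 64 genes an effect of dacapo cannot be told apart from a difference in strain background, including the chromosome that carries the transgene. The column headers give the control as pros-Gal4/+ and the other genotypes as pros-Gal4 over a UAS transgene, but do not describe the strains further.

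The lower level of mitosis genes in the stabilized forms was weighed next. The transcript length trend is argued against, since the median against dap was −0.41 after length correction and −0.36 before. Older embryos in the stabilized groups stay open, because the median of the cuticle list was −0.0117 (95% bootstrap interval over genes −0.08 to 0.06) with members moving both ways, and ages within the stage window are not given. The muscle list, also of a differentiated tissue, was higher than in dap with a median of 0.22, though not called with an estimated correlation. Whether embryo age caused that rise was not tested. Fewer dividing cells with stabilized Dacapo may account for the lower mitosis genes, and the DNA replication list was also lower than in dap, at −0.19 with 47 of 49 members below 0. Against the control that list stood at 0.0819 and was not called in any of the 3 forms with all 10 libraries (0.269, 0.782 and 0.159), while mitosis genes stood at −0.41, so that these explanations cannot be told apart in whole-embryo RNA.

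The third pattern was that calls in dap and dapCDI against the control followed transcript length. A trend arising between single libraries, such as RNA quality or library preparation, would give differences like the rho of 0.446 between the 2 dapCDI libraries, which share a genotype. Part of the trend was shared by both control libraries, with a rho of −0.0333 between them. From the shortest to the longest group their median deviations rose from −0.11 to 0.13 and from −0.14 to 0.09. For that part, genotype cannot be told apart from library preparation. Fewer or less mature neurons remain possible as a further part, since the length-corrected median of the neuronal list in dapCDI was −0.10. It rested on single libraries, since the deviation of that list from the mean of all libraries was then −0.14 in dapCDI 1, −0.00924 in dapCDI 2, 0.09 in dap 1 and −0.15 in dap 2, against 0.07 and 0.03 in the controls. That remainder cannot be told apart from an incomplete correction, because neuronal genes are long.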

How the results depend on the processing

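Length correction and the restriction to genes above the floor in every library were chosen after the results had been seen, while the other settings were planned. Of the 47 list calls, 47 held with log2(RPKM + 1), with the replicate block and above the floor, 46 with the stricter filter, 45 with only the groups compared, 44 without a mean-variance trend and 44 with centred libraries, 41 with quantile normalization, 37 without a filter and 34 after length correction. The totals called were 42 to 51 with 1 library left out. With a library left out, 433 list results held and 37 were lost, and 1275 results of named genes held, 731 were lost and 2 reversed, CycE not counted. After length correction 134 such results held, 60 were lost and 5 reversed, again without CycE.

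Counts of changed genes moved most, and except where stated the cause was not tested. Without a filter, which tests more genes, they were 292 in dap and 194 in dapCDI against the control. Against dap they were 66 in dapCRL4, 89 in dapPCNA and 39 in dapCDI, and 90 genes differed among stabilized forms. With the stricter filter they were 31 in dapCRL4, 209 in dapPCNA and 126 for the stabilized mean against dap. With log2(RPKM + 1) dapCRL4 against dap gave 39, above the floor it gave 31, and quantile normalization gave 132 for the stabilized mean. Without a mean-variance trend the counts were 193 in dap and 139 in dapCDI against the control, 8 in dapCRL4, 36 in dapPCNA, 3 in dapCDI and 14 for the mean against dap, and 7 among stabilized forms. The replicate block gave 253 in dapCDI against the control, and 8 in dapCRL4, 76 in dapPCNA, 7 in dapCDI (5 of them higher) and 45 for the mean against dap. Deviations of same-numbered replicates of different genotypes had correlations from −0.05 to 0.09, which leaves open whether such replicates were collected together. With only the groups compared, which leaves fewer samples, the counts were 92 in dapCRL4 and 43 in dapCDI against the control, 25 in dapPCNA, 1 in dapCDI and 35 for the mean against dap, and 3 among stabilized forms. In that limma fit dapCRL4 against dap gave 0, with 1549 genes at an unadjusted p under 0.05. Length correction gave 380 in dap and 311 in dapCDI against the control, and 37 in dapCRL4 and 33 in dapCDI against dap.

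With 1 library left out, which leaves fewer samples, counts against the control ran from 68 to 2225 in dap, 55 to 297 in dapCRL4, 71 to 174 in dapPCNA and 78 to 2595 in dapCDI. Against dap they ran from 1 to 64 in dapCRL4, 8 to 741 in dapPCNA, 1 to 37 in dapCDI and 5 to 547 for the stabilized mean, and from 6 to 230 among stabilized forms. In each of these comparisons the highest count came without a dapCDI library, the genotype whose replicates differed most.

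Some directions reversed. The CycE change in dapPCNA was 0.003295 with centred libraries and 0.0384 after length correction, and in dapCDI it was 0.15 after length correction. With 1 library left out CycE ran from −0.0786 to 0.29 in dap, −0.0874 to 0.18 in dapCRL4, −0.14 to 0.12 in dapPCNA and −0.19 to 0.0733 in dapCDI. After length correction Sxl and Mhc in dap stood at 0.00802 and 0.0521, and ago against dap at −0.00496 in dapCRL4, −0.0197 in dapPCNA and −0.0293 for the mean. The ago change in dapCDI against dap ran from −0.15 to 0.0436, the latter without dapCDI 1, and was also above 0 without dap 1. Depth limits genes under about 1 RPKM, where values rest on few reads and a gene listed at 0 may only be undetected.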

Other observations

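The test in this part was chosen after the result had been seen. Of the 14 genes differing among the stabilized forms, 10 lay on arm 2R (71.4%), which holds 20.6% of the 10252 tested genes with a position (Fisher's exact test, odds ratio 9.66, two-sided p = 6.02e-05). The dap gene, also on 2R, is among the 10. Whether a strain difference on this arm underlies these differences among the stabilized forms was not tested.

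Estimated depth per library ran from 17.0 to 25.7 counted megareads, against a range of 20.7 to 43.4 megareads in the labels.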
